A study of Homo sapiens with 6 samples.

How the data were processed

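Total RNA for 6 T47D libraries, 3 from cells with a PRL lentivirus and 3 from cells with the empty lentivirus, had been extracted with Trizol and sequenced with Illumina protocols, per the labels. The submitters' processing notes name HISAT2 2.1.0 and Bowtie2 2.3.4.3 and the genome build GRCh38.p13. The counting tool, the gene annotation, the selection of RNA and the use of strand are not given in the sources used here. With strand unknown, reads of overlapping genes on opposite strands cannot be told apart.

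The authors deposited 1 table of 17891 genes with NCBI gene IDs and symbols and, for each library, an estimated count, an FPKM and a TPM value, per the file headers. The deposited read counts were expected (estimated) counts: 44.1% to 45.9% of values per library were not whole. They were rounded to whole numbers here before testing. The deposited FPKM values are scaled to fragments per kilobase and library size, and the deposited TPM values to length and the sum of all transcripts, both by the authors, per the file headers. The authors' group means, 6 columns, were not used. All 18 columns of single libraries matched the sample titles.

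Samples were grouped by their titles. Rounded counts summed to 17402348, 16432849 and 16949521 in the control libraries and 16343163, 16646457 and 16211146 in the PRL libraries. A level of 0 allows up to 3 counts per library, or 0.165 to 0.203 CPM. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules.

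Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit, robust, group as the only term), after edgeR's filter on low counts by group and TMM scaling, which left 14076 genes. Adjusted p-values are Benjamini-Hochberg values over these genes with a threshold of 0.05. Standard errors were computed as the absolute log2 fold change divided by the root of the F statistic. A fold against a group at 0 was computed against 3 counts per library. Ratios for genes with under 10 counts in 1 group carry exact 95% intervals from the binomial division of counts. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over 26 lists, with an estimated correlation and fry as alternatives. Correlation estimates rest on few residual degrees of freedom.

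Of 27 lists fixed before the data were examined, the mitochondrially encoded genes were not analysed here. The others covered the prolactin receptor and JAK2-STAT5 pathway, prolactin-STAT5 targets, milk and mammary secretory genes, estrogen response, luminal, basal and stem-like markers, epithelial-mesenchymal transition, mitosis, DNA replication, interferon-stimulated genes, antigen presentation, NF-kB, MAPK immediate early genes, cholesterol and fatty acid synthesis, glycolysis and hypoxia, the unfolded protein response, ATF4 and p53 targets, TGF-beta targets, oxidative phosphorylation, ribosomal proteins, replication-dependent histones, stromal and immune markers, and pituitary markers. Genes were named by a rule fixed at the same time. It took PRL; the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose higher group averaged at least 5 CPM; and the 4 members of each list with the smallest adjusted p. A gene named by more than 1 part counts under each. Single values of 5 list members that the rule named are not reported here, and the counts and tests of their lists include them.

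Alternatives fixed before the data were examined were other scalings (DESeq2's size factors, upper quartile, library totals, PRL left out), no filter or CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, and limma with a trend on log2 FPKM or TPM with a pseudocount of 1 and a mean of at least 1. Added after seeing the data were runs without ribosomal protein genes and with each library's trend on GC content and length removed (mgcv 1.9.3). The removed fit included each library's mean, so that run also recentred the libraries. GC content came from GENCODE release 29 transcripts, matched through NCBI gene ID for 97.8% of genes, and length from the ratio of the deposited counts to FPKM. Both were known for 93.2% of tested genes. Coordinates and exon overlaps are from GENCODE 29 on GRCh38.

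The tests were checked on simulated counts with each gene's mean over all 6 libraries and this comparison's trend of spread. Changes of 1.5-fold, 2-fold and 4-fold were given to 65, 67 and 64 of 13915 tested genes. Of these, 47 (72.3%), 55 (82.1%) and 64 were called, and 10 of 13719 unchanged genes were called. The simulation gave both groups the same spread and changed few genes. These rates need not hold in the real data, where controls varied more and 8854 of 14076 genes changed. In simulated data camera called 0 of 26 lists with none changed, and the raised list alone when 1 list was raised 2-fold. The simulated genes varied independently of one another. This check therefore says nothing about lists whose genes vary together, such as the ribosomal protein list with an estimated correlation of 0.918.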

Results

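RNA of T47D cells was measured by RNA sequencing in 6 libraries. T47D is an established human line of luminal, estrogen receptor-positive breast cancer that carries the prolactin receptor. In the PRL group (3 libraries) the cells had been transduced with a puromycin-selectable lentivirus that carries PRL, the gene of the pituitary and mammary hormone prolactin. In the control group (3 libraries) they had received the empty lentivirus. The series describes the 3 libraries of each group as biological replicates. Libraries held 16211146 to 17402348 estimated gene counts, so that 1 count stood for 0.0551 to 0.0678 CPM. Levels are given as mean ± SD of CPM scaled by the trimmed mean of M values (TMM) over the 3 libraries of a group (n = 3), and fold changes as PRL over control on the log2 scale with their standard error (SE).

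Prolactin transcript itself separated the groups, in the direction of the labels. PRL (NCBI gene 5617, GRCh38 chromosome 6, 22287244 to 22297501, minus strand, 5 exon blocks) had 3, 3 and 1 counts in the control libraries and 8277, 8097 and 7789 in the PRL libraries. Its level was 0.152 ± 0.0781 CPM in controls and 449.6 ± 7.63 CPM in the PRL group (log2 fold change 11.47, SE 0.16, adjusted p = 2.0e-11 by edgeR's quasi-likelihood test). The ratio of counts was 2984, with a 95% counting interval of 1448 to 7423. Reads of the lentiviral copy cannot be assigned to the genomic locus, since both carry the same coding sequence. The transcript of its receptor, PRLR, did not pass the test, with a log2 fold change of 0.27 (SE 0.12, edgeR adjusted p = 0.0724).

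The comparison of the groups asked which transcripts differ in T47D cells that overexpress prolactin. Of 14076 genes tested, 8854 changed at an adjusted p under 0.05 in edgeR, 4554 higher and 4300 lower in the PRL group, and 2231 of them by at least 2-fold (1486 higher, 745 lower). Larger changes lay mostly on the side of a rise: 502 genes were at least 4-fold higher and 77 at least 4-fold lower. For 9782 genes, 69.5% of those tested, all PRL libraries lay on one side of all control libraries, where chance gives 10%. The first principal component held 84.2% of the variance and separated the groups. On it the controls lay at -61.0, -52.1 and -43.5 for replicates 1 to 3, and the PRL libraries at 51.3 to 52.9.

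The control libraries differed more among themselves than the PRL libraries did. Control replicate 3 correlated with the PRL libraries at 0.944 to 0.945 in log2 CPM, control replicates 1 and 2 at 0.926 to 0.931. A chi-square comparison of counts gave 13.4 to 25.7 per gene for pairs of controls and 1.68 to 2.22 for pairs of PRL libraries, where sampling noise alone gives about 1, so no pair agreed within sampling noise. The sources used here do not tell whether the PRL libraries came from separate transductions or cultures. If they did not, the SDs and p-values cover less than the variation between cultures. Ribosomal protein genes took 16.7% ± 1.66 of counts in controls and 10.4% ± 0.287 in the PRL group. TMM factors were unequal as well (0.916 ± 0.0591 and 1.09 ± 0.0121). Scaling by library totals moved the median log2 fold change of all genes from 0.01 to 0.26, and the share of changed genes that were higher from 51.4% to 72.9%. That share was 69.9% from FPKM, 83.7% from TPM and 40.2% after each library's trend on GC content and length was removed. The removed fit held each library's mean too, so this run recentred the libraries, and 40.2% is not the effect of the trend alone. The median log2 fold change of all genes was 0.20 from FPKM, 0.39 from TPM and -0.11 in that run. List medians and calls of single genes in these settings carry such shifts. Changes are stated relative to the TMM scale.

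**Figure D1:**
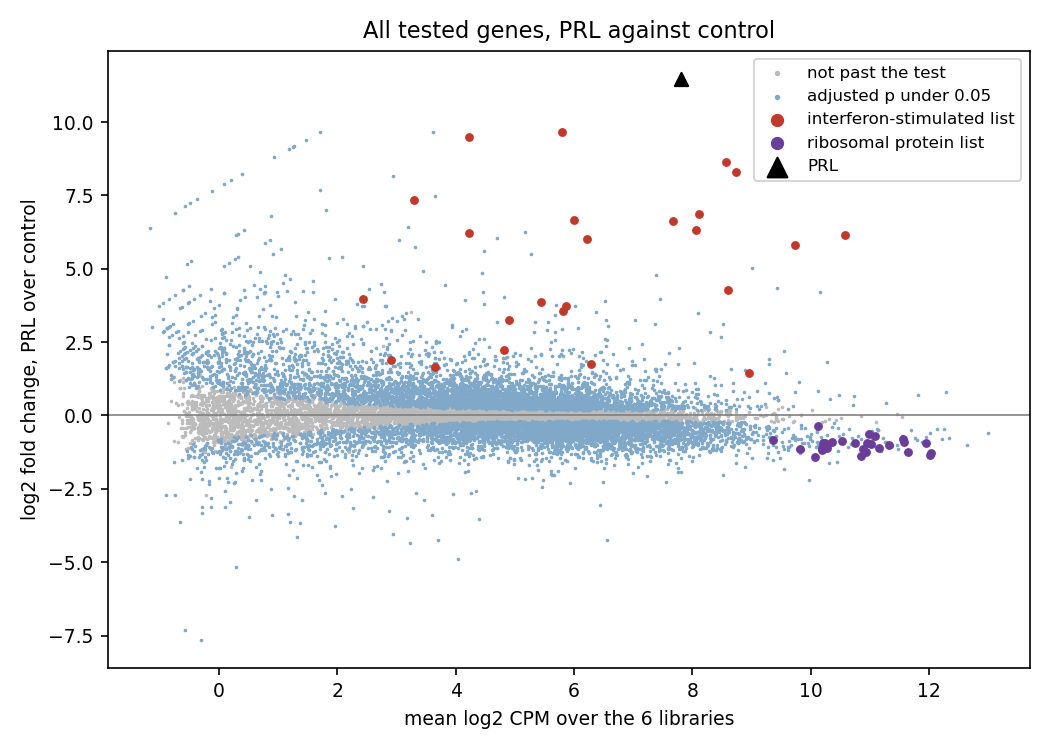
Log2 fold change (PRL over control, vertical axis) against mean log2 CPM over the 6 libraries (horizontal axis) for the 14076 tested genes. Blue points passed the edgeR test (8854 genes). The interferon-stimulated list (red) lies above 0, the ribosomal protein list (purple) lies below 0 at high expression, and the triangle is PRL at 11.47.

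Among the largest rises were 5 genes of the interferon response. IFI44 (0.131 ± 0.0705 to 110.2 ± 4.87 CPM), IFI44L (0.0439 ± 0.038 to 36.4 ± 1.35 CPM), IFI27 (1.92 ± 1.06 to 758 ± 41.8 CPM), OAS2, an antiviral oligoadenylate synthetase (2.71 ± 0.149 to 848 ± 8.78 CPM), and CMPK2 (0.108 ± 0.0387 to 18.6 ± 1.11 CPM) rose, with log2 fold changes of 9.66, 9.49, 8.62, 8.29 and 7.34. Their edgeR adjusted p ranged from 2.0e-11 for OAS2 to 2.7e-09 for CMPK2. PTHLH, which encodes parathyroid hormone-related protein, had 0 counts in every control library and 5.98 ± 0.583 CPM in the PRL group, at least 30.8-fold higher against a floor of 3 counts per library (edgeR adjusted p = 1.4e-06). SOCS2, a feedback inhibitor of prolactin and growth hormone signalling, had 2 counts over the controls and 344 over the PRL libraries, a ratio of 149 (95% counting interval 40.8 to 1233, edgeR adjusted p = 3.1e-07). The class II antigen gene HLA-DRA (ratio 338, interval 93.1 to 2792), the acute-phase gene SAA1 (ratio 278, interval 49.6 to 11028) and the galectin gene LGALS9 (ratio 187, interval 85.6 to 509.7) rose as well, with edgeR adjusted p of 9.2e-09, 2.8e-07 and 3.0e-08. Without control replicate 2, which holds the 1 control count of SAA1 and most of those of LGALS9, the fitted log2 fold changes of these genes were 9.66 and 9.24, against 7.69 and 7.46 with all libraries.

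The rule also named CHTF8 and BIVM-ERCC5, whose levels are uncertain. CHTF8 had 1 control count and 23.6 ± 4.004 CPM in the PRL group (ratio 1097, interval 197 to 43362, edgeR adjusted p = 1.8e-08), and its fitted log2 fold change was 9.67, or 11.64 without control replicate 3, which holds that count. DERPC, a gene that shares transcripts with CHTF8, lay 26.6 CPM lower in the PRL group, at 96.2 ± 10.3 CPM in controls and 69.5 ± 1.79 CPM in the PRL group. BIVM-ERCC5 is the readthrough of BIVM and ERCC5 and shares its exons with them. It had 0 control counts and at least 26.0-fold higher level in the PRL group (5.04 ± 1.74 CPM, edgeR adjusted p = 2.3e-05), while ERCC5 (log2 fold change -0.02) and BIVM (-0.06) did not pass the test.

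The largest falls included CLDN1, a tight junction claudin, from 179.7 ± 24.1 to 9.41 ± 0.643 CPM (log2 fold change -4.25, SE 0.12, edgeR adjusted p = 1.6e-09). It lies on GRCh38 chromosome 3 from 190305701 to 190322475. TENM3, a teneurin adhesion receptor, fell from 155 ± 16.3 to 18.9 ± 1.01 CPM (log2 fold change -3.03), and KCNK5, a potassium channel gene, from 39.3 ± 3.54 to 3.42 ± 0.485 CPM (-3.52), with edgeR adjusted p of 5.2e-09 and 1.1e-08. The lectin-like receptor gene OLR1 (-4.33), its neighbour TMEM52B (-4.04), the transcription factor gene LYL1 (-4.23), the transcriptional cofactor gene VGLL1 (-3.76), the troponin gene TNNC1 (-3.51), XAGE2 (-3.39) and FGD5 (-3.26) also fell, with edgeR adjusted p from 3.0e-08 for TMEM52B to 9.8e-06 for LYL1. CXCR5, at -4.90 (SE 0.96, edgeR adjusted p = 0.0058), was scattered in controls at 32.5 ± 24.2 CPM and lay at -4.27 without control replicate 2, and 88.6% of its exon bases are overlapped by BCL9L on the opposite strand. HSPE1-MOB4, a readthrough gene whose exons all belong to HSPE1 or MOB4 too, had 8.67 ± 4.95 and 0.957 ± 0.872 CPM (log2 fold change -3.16, edgeR adjusted p = 0.0034), and -3.87 without PRL replicate 2. Its call ended with the replicate number as a block (edgeR adjusted p = 0.157).

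**Figure D2:**
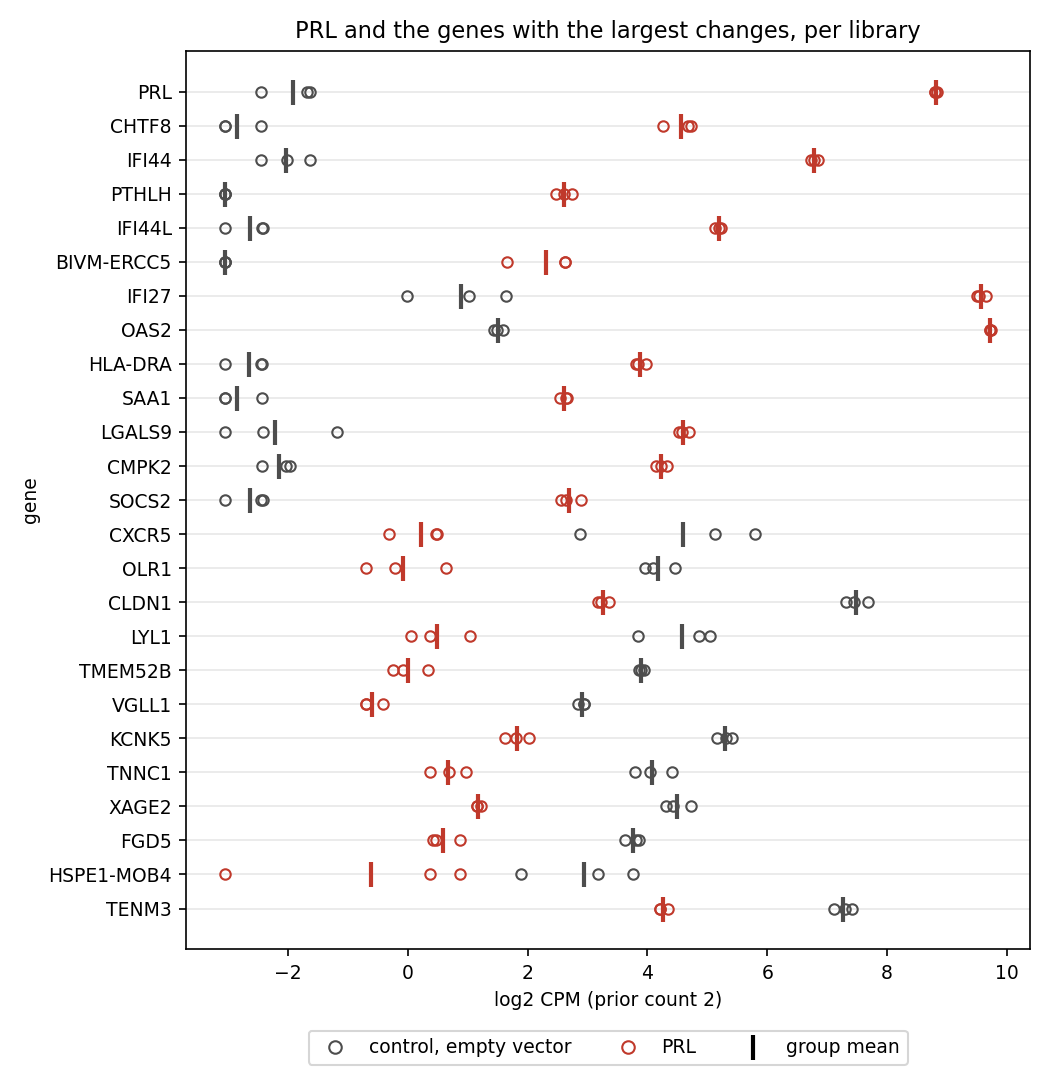
Expression per library of PRL and of the 12 genes with the largest rise and the 12 with the largest fall that met the naming rule. The horizontal axis is log2 CPM with a prior count of 2, circles are libraries (grey, control; red, PRL) and bars are group means. The naming rule took only rises and falls whose PRL and control libraries do not overlap, and for the PRL gene they do not overlap either.

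Genes of the prolactin signalling path and its STAT5 targets rose more often than they fell. Of 17 tested members of the prolactin receptor and JAK2-STAT5 list, 9 rose, 1 fell and 7 did not pass (camera adjusted p = 0.0050, and adjusted p = 0.439 with an estimated correlation). STAT5A, the transcription factor that the receptor activates through JAK2, rose from 1.38 ± 0.281 to 10.6 ± 0.417 CPM (log2 fold change 2.94, SE 0.17, edgeR adjusted p = 3.4e-07). The adaptor genes GAB2 (2.04) and SHC1 (0.90) rose as well, with edgeR adjusted p of 2.2e-07 and 4.5e-06. In the prolactin-STAT5 target list 13 of 18 tested genes rose and 3 fell (camera adjusted p = 0.0074, and adjusted p = 0.231 with an estimated correlation). The list does not record whether STAT5 raises or lowers each gene, so these counts do not measure STAT5 activity. BCL6 rose from 55.8 ± 5.37 to 164 ± 4.71 CPM and CISH, another feedback inhibitor, from 26.1 ± 0.76 to 62.3 ± 3.30 CPM, beside SOCS2. ID1 fell from 29.3 ± 3.001 to 7.84 ± 0.741 CPM. The edgeR adjusted p were 2.7e-07, 6.5e-07 and 5.3e-07. The call for the target list ended on the FPKM (adjusted p = 0.0941) and TPM values (0.157).

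Secreted products of the breast epithelium went in both directions. In the milk and mammary secretory list 7 of 12 tested genes rose and 1 fell (camera adjusted p = 0.0337, and adjusted p = 0.439 with an estimated correlation), with a median log2 fold change of 0.69, also with PTHLH at its bound. PIP, the prolactin-inducible protein gene, rose from 119 ± 6.77 to 2179 ± 109 CPM (log2 fold change 4.20, SE 0.10, edgeR adjusted p = 8.4e-10), and AZGP1 from 98.9 ± 6.04 to 335 ± 10.3 CPM (1.76, edgeR adjusted p = 5.6e-08). CLU, which encodes the secreted chaperone clusterin, fell from 1649 ± 158 to 359 ± 7.36 CPM (-2.20, edgeR adjusted p = 5.8e-08). The list's camera call ended without control replicate 3 (adjusted p = 0.0864), with the stricter filter (0.0740), with library totals (0.108) and on FPKM (0.0886) and TPM (0.148).

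Interferon-stimulated genes were the list with the strongest rise: all 24 rose, with a median log2 fold change of 5.91, a 60.1-fold difference, or 3.65 on FPKM with its pseudocount of 1 (camera adjusted p = 5.4e-17, and adjusted p = 0.106 with an estimated correlation). IFIT1 rose from 4.73 ± 0.361 to 549 ± 16.6 CPM, OAS1 from 4.05 ± 0.486 to 404 ± 3.14 CPM and MX1, an antiviral GTPase, from 29.6 ± 0.301 to 1667 ± 12.6 CPM, with edgeR adjusted p of 2.7e-11, 3.7e-11 and 5.2e-11. OAS2 (NCBI gene 4939) lies on GRCh38 chromosome 12 from 112978395 to 113011723, and MX1 (NCBI gene 4599) on chromosome 21 from 41420304 to 41459214. Antigen presentation genes rose too, with 14 of 17 higher, none lower and a median of 1.83 (camera adjusted p = 1.1e-06, and adjusted p = 0.106 with an estimated correlation). HLA-C rose from 259 ± 10.4 to 991 ± 11.9 CPM and HLA-F from 15.2 ± 0.932 to 119 ± 1.14 CPM, with edgeR adjusted p of 3.5e-08 and 1.3e-09. Class I HLA genes resemble one another, so the division of reads among them is uncertain. CIITA, the activator of class II genes, had a log2 fold change of -0.24 (edgeR adjusted p = 0.0941).

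NF-kB and inflammatory genes rose in 7 of 9 tested members, and none fell (median log2 fold change 2.05, or 1.38 in DESeq2 over all 18 members, camera adjusted p = 6.1e-04, and adjusted p = 0.176 with an estimated correlation). ICAM1, a leukocyte adhesion molecule, went from 3.15 ± 0.561 to 26.6 ± 0.684 CPM, the inhibitor gene NFKBIA from 42.6 ± 0.836 to 116 ± 1.02 CPM, NFKB2 from 67.4 ± 4.75 to 173 ± 5.11 CPM and RELB from 2.78 ± 0.278 to 11.6 ± 0.515 CPM, with edgeR adjusted p of 3.4e-08, 9.3e-08, 3.9e-07 and 9.3e-07. Of 19 tested MAPK immediate early and feedback genes 12 rose and 1 fell (median 1.26, camera adjusted p = 2.4e-04, and adjusted p = 0.106 with an estimated correlation). IER3 rose from 76.6 ± 6.96 to 661 ± 22.1 CPM, JUN from 22.2 ± 2.89 to 89.9 ± 1.29 CPM, DUSP1 from 4.32 ± 0.817 to 28.6 ± 1.28 CPM and ATF3 from 14.1 ± 1.32 to 50.4 ± 1.35 CPM, with edgeR adjusted p from 2.8e-09 to 1.1e-07.

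Genes of DNA replication and mitosis fell. In the DNA replication list 18 of 20 fell and none rose (median log2 fold change -0.83, camera adjusted p = 5.5e-06, and adjusted p = 0.304 with an estimated correlation). MCM5, a subunit of the replicative helicase, fell from 97.1 ± 11.5 to 37.5 ± 1.30 CPM, MCM3 from 258 ± 6.84 to 145 ± 5.24 CPM, GINS1 from 42.3 ± 1.22 to 20.2 ± 0.347 CPM and GINS2 from 232 ± 31.7 to 98.7 ± 3.80 CPM, with edgeR adjusted p from 1.3e-06 to 6.0e-06. In the mitosis list 14 of 20 fell and none rose (median -0.47, or -0.02 on TPM, camera adjusted p = 1.6e-04, and adjusted p = 0.304 with an estimated correlation). AURKB fell from 124 ± 13.03 to 57.7 ± 3.79 CPM and CDC20, an activator of the anaphase-promoting complex, from 253 ± 35.1 to 111 ± 2.58 CPM. CENPF and PLK1 fell as well, by 0.72 and 0.60 on the log2 scale. The 4 edgeR adjusted p ranged from 5.5e-06 to 4.8e-05, and CENPF and PLK1 did not pass in limma on TPM (adjusted p = 0.0894 and 0.183). On TPM the median of all genes was 0.39, and the mitosis list kept its camera call.

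Transcripts for the protein synthesis machinery and the respiratory chain were lower in the PRL group. All 28 cytoplasmic ribosomal protein genes fell (median log2 fold change -0.99, camera adjusted p = 6.5e-10, and adjusted p = 0.439 with an estimated correlation), for example RPL5 (1566 ± 256 to 586 ± 19.8 CPM), RPL7 (2674 ± 420 to 1034 ± 34.5 CPM), RPS6 (2619 ± 333 to 1179.8 ± 35.7 CPM) and RPLP1 (2751 ± 439 to 1168 ± 16.2 CPM), with edgeR adjusted p from 5.3e-06 to 1.4e-05. These genes have many processed pseudogenes, and reads shared with them make single levels uncertain. In the oxidative phosphorylation list 18 of 24 nuclear genes fell and 1 rose (median -0.63, or -0.17 on TPM, camera adjusted p = 1.6e-04, and adjusted p = 0.439 with an estimated correlation). ATP5MC1 fell from 376 ± 60.0 to 141 ± 7.15 CPM, UQCRQ from 309 ± 62.0 to 147 ± 6.92 CPM, NDUFA4 from 340 ± 41.7 to 193 ± 7.31 CPM and COX5A from 173 ± 14.3 to 104 ± 5.94 CPM, with edgeR adjusted p from 3.5e-06 to 4.6e-05. Transcripts whose levels can depend on RNA selection, among other things, moved with the groups too. All 8 tested replication-dependent histone genes, whose main transcripts lack a poly(A) tail, rose (median 1.02, camera adjusted p = 0.0049, and adjusted p = 0.308 with an estimated correlation), among them H2BC5 (34.1 ± 4.27 to 62.2 ± 1.86 CPM), H2BC4 (1.46 ± 0.268 to 6.57 ± 1.56 CPM), H2BC8 (1.52 ± 0.678 to 4.43 ± 0.392 CPM) and H4C8 (0.256 ± 0.102 to 1.06 ± 0.206 CPM), with edgeR adjusted p from 2.8e-05 to 0.00135. The share of counts on MTRNR2L genes, which resemble mitochondrial ribosomal RNA, was 0.795% ± 0.0252 in controls and 1.59% ± 0.0223 in the PRL group. Mitochondrially encoded genes were not analysed here.

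Genes of low oxygen, protein folding and amino acid shortage rose in part. In the glycolysis and hypoxia list 18 of 26 rose and 4 fell (median log2 fold change 0.56, camera adjusted p = 0.0019, and adjusted p = 0.506 with an estimated correlation). The clearest rises were HK2 (14.5 ± 3.09 to 82.4 ± 1.498 CPM), the glucose transporter gene SLC2A1 (32.0 ± 6.09 to 143 ± 3.88 CPM), ENO2 (7.49 ± 0.844 to 27.7 ± 0.369 CPM) and PFKFB4 (21.2 ± 5.02 to 98.8 ± 2.04 CPM), with edgeR adjusted p from 1.2e-07 to 6.8e-07. Of 21 unfolded protein response genes 16 rose and 2 fell (median 0.60, camera adjusted p = 9.2e-04, and adjusted p = 0.176 with an estimated correlation). DDIT3 rose from 19.6 ± 0.717 to 91.5 ± 5.02 CPM, the chaperone gene HSPA5 from 557 ± 34.6 to 1235 ± 20.3 CPM, HERPUD1 from 34.9 ± 2.42 to 88.8 ± 2.66 CPM and DNAJB9 from 6.59 ± 0.667 to 18.3 ± 0.947 CPM, with edgeR adjusted p from 1.1e-08 to 2.8e-06. In the ATF4 amino acid response list 15 of 19 rose and 3 fell (median 0.74, camera adjusted p = 9.2e-04, and adjusted p = 0.116 with an estimated correlation). DDIT4 rose from 73.6 ± 14.6 to 363 ± 7.38 CPM, ASNS from 31.9 ± 1.91 to 77.7 ± 0.114 CPM and GDF15 from 0.427 ± 0.229 to 6.85 ± 0.557 CPM, while STC2 fell from 594 ± 32.4 to 144 ± 5.33 CPM, with edgeR adjusted p from 2.5e-08 to 1.3e-06. Other annotated genes overlap 41.2% of the exon bases of DDIT4, 44.6% of those of ASNS and, on the opposite strand, 31.6% of those of DDIT3, so their levels are less certain. The same limit holds, on the opposite strand, for IER3 (26.5%), HLA-F (28.5%), ICAM1 (23.6%) and UQCRQ (20.8%). It also holds for ACTA2 (30.1%), LYZ (34.0%) and LHX4 (30.8%).

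Lineage markers went both ways. The estrogen response list had 12 genes higher, 8 lower and 4 that did not pass (camera adjusted p = 0.837). AREG, a ligand of the epidermal growth factor receptor, rose from 34.2 ± 4.79 to 294 ± 2.96 CPM and MYB from 15.3 ± 1.38 to 33.6 ± 0.489 CPM, whereas TFF3 fell from 35.2 ± 6.75 to 5.87 ± 0.611 CPM. Luminal markers divided evenly, 9 higher and 9 lower of 20 (camera adjusted p = 0.720, fry adjusted p = 0.0029, on balance lower), with a median log2 fold change of -0.04, or 0.41 on TPM. The median of all genes on TPM was 0.39. AGR2 fell from 1175 ± 115 to 334 ± 4.98 CPM and AGR3 from 66.2 ± 7.45 to 18.2 ± 1.01 CPM, while the E-cadherin gene CDH1 rose from 155 ± 15.5 to 248 ± 2.53 CPM. Across these 6 genes the edgeR adjusted p ranged from 5.6e-09 to 7.4e-05. Basal and myoepithelial markers had 3 higher and 3 lower of 9 (camera adjusted p = 0.818), with ACTA2 (log2 fold change -1.01), EGFR (-0.93) and TAGLN (-0.90) lower and TP63 (1.25) higher, at edgeR adjusted p from 2.4e-05 to 0.0025. In limma on TPM the calls of EGFR (adjusted p = 0.493) and TAGLN (0.0933) ended.

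Of 12 tested epithelial-mesenchymal transition genes 7 rose and 2 fell (median log2 fold change 1.19, camera adjusted p = 0.0337, and adjusted p = 0.231 with an estimated correlation). The fibronectin gene FN1 rose from 20.6 ± 5.64 to 88.4 ± 1.03 CPM, LOX from 1.11 ± 0.326 to 6.35 ± 0.226 CPM, SNAI1 from 2.15 ± 0.193 to 7.57 ± 0.382 CPM and ITGA5 from 13.5 ± 1.95 to 31.9 ± 0.631 CPM, with edgeR adjusted p from 1.5e-06 to 7.0e-06. The list's call ended without control replicate 3 (camera adjusted p = 0.0948), without a count filter (0.166), with library totals (0.108) and on FPKM (0.115) and TPM (0.242). Breast stem-like markers had 6 of 11 higher and 3 lower (camera adjusted p = 0.2998, fry adjusted p = 0.0019, on balance higher). KLF4 rose from 2.68 ± 1.36 to 17.7 ± 0.384 CPM, SOX2 from 2.36 ± 0.294 to 11.4 ± 1.15 CPM, BMI1 from 0.77 ± 0.253 to 5.48 ± 0.788 CPM and NOTCH1 from 13.4 ± 1.19 to 28.9 ± 1.08 CPM, with edgeR adjusted p from 1.2e-06 to 7.7e-06, and 23.4% of the exon bases of BMI1 are shared with a readthrough gene.

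Lipid, p53 and TGF-beta lists did not pass camera. Cholesterol synthesis had 9 genes higher and 8 lower of 21 (camera adjusted p = 0.847), with EBP (238 ± 44.5 to 111 ± 1.94 CPM) lower and MSMO1 (44.1 ± 5.44 to 82.0 ± 1.88 CPM) higher, at edgeR adjusted p of 2.8e-05 and 2.0e-05. Fatty acid synthesis had 8 higher and 3 lower of 18 (camera adjusted p = 0.538, fry adjusted p = 0.0096, on balance higher). Its median was 0.07, or -0.11 with the GC and length trend removed, where the median of all genes was -0.11 as well. DGAT2 (log2 fold change 1.74), THRSP (1.78) and DGAT1 (0.52) were higher and ACACA (-0.55) lower, at edgeR adjusted p from 7.0e-07 to 1.8e-04. ACACA did not pass in limma on TPM (adjusted p = 0.506). The p53 target list had 9 higher and 7 lower of 18 (camera adjusted p = 0.444, fry adjusted p = 4.2e-04, on balance higher), where the cell cycle inhibitor gene CDKN1A (23.9 ± 1.36 to 81.0 ± 1.69 CPM), GDF15, BBC3 (1.35) and BTG2 (1.20) rose, at edgeR adjusted p from 4.6e-08 to 1.7e-05. TGF-beta targets had 5 higher and 4 lower of 15 (camera adjusted p = 0.895), with the receptor gene TGFBR1 lower (63.9 ± 1.85 to 19.96 ± 0.756 CPM) and TGFB1 (1.60), TGIF1 (1.04) and BAMBI (0.92) higher, at edgeR adjusted p from 6.3e-08 to 4.5e-05.

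Markers of other cell types did not pass camera. Stromal and immune markers had 4 higher and 1 lower of 9 tested (camera adjusted p = 0.460, fry adjusted p = 0.0299, on balance higher). CD68, which epithelial cells also express, rose from 3.54 ± 0.475 to 15.1 ± 0.441 CPM and COL1A1 from 50.2 ± 8.25 to 71.3 ± 0.129 CPM, with edgeR adjusted p of 6.1e-07 and 0.0020, and 81.7% of the exon bases of CD68 are shared with another annotated gene. LYZ fell (136 and 82 counts over the libraries of each group, log2 fold change -0.94, edgeR adjusted p = 0.0119) and CD14 rose (17 and 49 counts, 1.30, edgeR adjusted p = 0.0142), both at low levels. Both lost their call without control replicate 1 (edgeR adjusted p = 0.0519 and 0.0520), LYZ also without PRL replicate 1 (0.0543) and on TPM (0.0781 in limma), and CD14 without PRL replicate 3 (0.0520) and in DESeq2 (0.0692). Pituitary markers had 1 higher and 1 lower of 4 tested (camera adjusted p = 0.818). PITX1 fell from 211 ± 23.3 to 137 ± 4.95 CPM, TBX19 rose from 0.373 ± 0.266 to 1.30 ± 0.507 CPM (log2 fold change 1.80, and 2.52 without control replicate 1), and LHX4 (0.21) and LHB (0.47) did not pass, with edgeR adjusted p of 1.9e-04, 0.0074, 0.162 and 0.285 in that order. In limma on TPM the call of PITX1 ended (adjusted p = 0.0655), while LHX4 (0.0141) and LHB (0.0096) passed, as LHX4 did with library totals (0.0220) and both did on FPKM (0.0407 and 0.0347).

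In all, 16 of the 26 tested lists passed camera with its preset correlation, 12 higher and 4 lower. None passed with an estimated correlation (6 had an unadjusted p under 0.05), and 21 passed fry, which asks whether a list's own genes move one way on balance. The 5 lists past fry and not camera were the luminal, stem-like, fatty acid, p53 and stromal and immune lists. Counts of members adjusted over the list alone were the same as those over all genes in 25 lists, and in the cholesterol list 10 rather than 9 genes rose. Median, mean and camera direction differed in sign in 4 lists without a call. These were the estrogen response (median 0.25, mean -0.06), basal (0.01 and -0.02), cholesterol (-0.05 and 0.01) and TGF-beta (-0.04 and 0.10) lists.

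**Figure D3:**
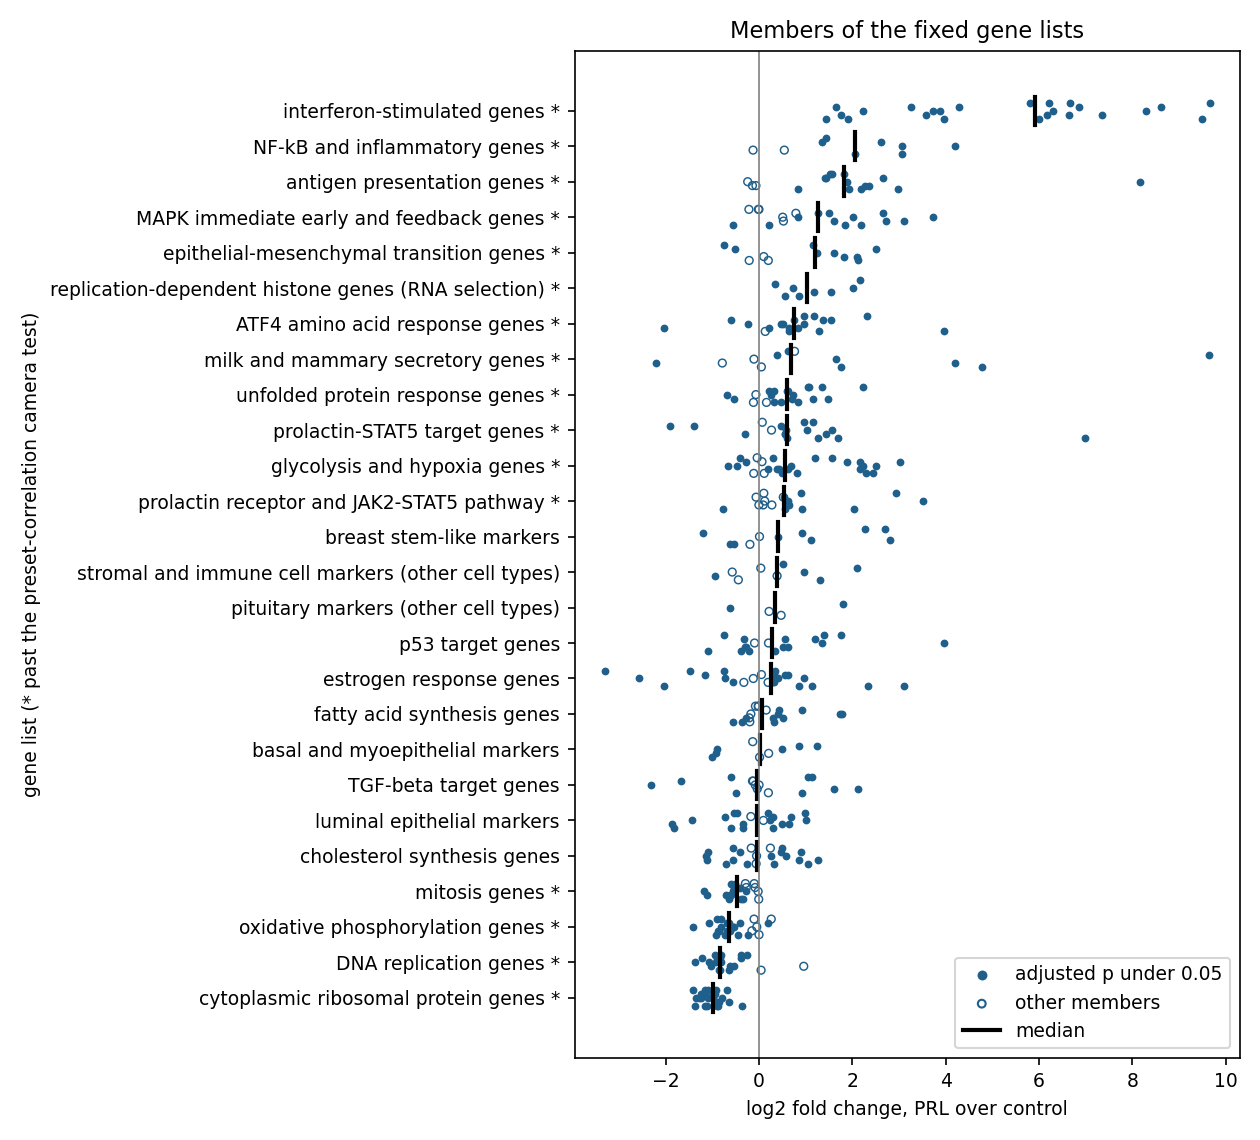
Log2 fold change (PRL over control, horizontal axis) of each tested member of the 26 gene lists, sorted by median. Filled circles are members with an edgeR adjusted p under 0.05, open circles the other members, black bars the medians, and asterisks mark the 16 lists past camera with its preset correlation. Medians range from -0.99 for ribosomal protein genes to 5.91 for interferon-stimulated genes.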

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

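The count of changed genes (8854) lay between 7834 and 9126 under the other scalings, filters, units and tools, and between 7590 and 9952 with 1 library left out. PRL stayed higher, at 8.97 to 11.80 on the log2 scale, and at 11.12 to 11.72 with 1 library left out. The direction split differed between settings. Genes lower in the PRL group numbered 2394 with library totals, 2360 from FPKM and 1381 from TPM, against 4300, and genes higher numbered 7113 from TPM, against 4554. These 3 settings place the median gene at 0.26, 0.20 and 0.39. Library totals changed the scaling alone, while FPKM and TPM also changed the filter, pseudocount and tool, and the cause of their difference was not tested. Genes changed by at least 2-fold fell to 1091 from FPKM, against 2231, where the cause was not tested either. With 1 library left out, genes higher ranged from 3929 to 5264, genes lower from 3653 to 4688, and genes changed at least 2-fold from 2006 to 2775. Of the 16 lists past camera, 13 to 16 passed under other scalings, filters and units and 14 to 16 with 1 library left out, but 0 with an estimated correlation in limma (6 at an unadjusted p under 0.05) and 21 in fry. The lost lists were milk genes, epithelial-mesenchymal transition genes and, on FPKM and TPM, STAT5 targets.

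No label says that replicate numbers pair samples, so the numbers were not taken as pairs. Samples with the same number did not deviate together (correlations -0.105, 0.043 and -0.057, with 2 of 6 libraries closest to their own number). With 3 libraries per group this check can hardly decide on pairing. With the replicate number as a block, 8531 genes changed (4423 higher, 4108 lower, 2224 by at least 2-fold), 16 lists passed, and PRL lay at 11.47. HSPE1-MOB4 did not pass in that fit (edgeR adjusted p = 0.157). For the 122 named genes besides PRL, HSPE1-MOB4 included, 2298 values under 19 alternatives held 0 reversals, 13 lost calls and 5 gained calls, and 2280 kept theirs. The cause of these changes was not tested. Runs without ribosomal protein genes (8775 genes changed) and with the GC and length trend removed (8859 changed, 3560 higher and 5299 lower) were chosen after seeing the data. The latter run also recentred each library, so its split does not show the trend alone. Only 75% of tested milk genes had GC content and length, so that correction is void for this list. The alternatives for tables without counts (a pseudocount of 0.1, no filter on low values) were not run, since counts were given. Depth limits genes near 3 counts per library.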

Other observations

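Genes in this part were picked after their values were seen, and all of its tests except the counts of sample splits were chosen after the results. The type III interferon gene IFNL1 (GRCh38 chromosome 19, 39296325 to 39298673) had 0 counts in each control library and 67, 70 and 82 in the PRL libraries, at least 21.0-fold higher. IFNL2 and IFNL3, near-identical copies whose reads are hard to divide, had 2 and 1 counts over the controls and 160 and 123 over the PRL libraries. The type I gene IFNB1 had 0 counts in controls and 3, 7 and 7 in the PRL libraries and was not tested. IRF9 (log2 fold change 2.92, edgeR adjusted p = 5.6e-09), TNFSF10, the death ligand gene (2.96, edgeR adjusted p = 2.0e-09), IFITM1 (5.02, edgeR adjusted p = 8.4e-10) and LGALS3BP (4.36, edgeR adjusted p = 6.8e-10) rose, and the kinase gene JAK1 fell (-1.32, edgeR adjusted p = 9.7e-07). All 3 PRL libraries lay on the stated side for each tested gene here that rose or fell.

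The clock genes PER1 (1.68) and NR1D1 (1.99), the glucocorticoid-responsive TSC22D3 (2.07), the insulin receptor substrate IRS1 (2.46) and DEPTOR, an inhibitor of mTOR (1.95), rose, with edgeR adjusted p from 9.1e-08 to 1.2e-06. The fatty acid carrier CD36 rose from 20.5 ± 2.66 CPM (SD, n = 3) by 3.05 on the log2 scale and ANGPTL4 by 3.26, and IGFBP5 (-1.92), FGFR2 (-1.66) and GFRA1, a neurotrophic factor receptor (-1.94), fell, with edgeR adjusted p from 4.5e-09 to 1.0e-06. The psoriasin gene S100A7 had 0 counts in controls and 56, 67 and 59 in the PRL libraries, at least 17.5-fold higher.

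The rise of interferon-stimulated genes was set against 2 technical explanations and 1 biological one. Once each library's trend on GC content and length was removed, the list's median log2 fold change was 5.76, against 5.91, which argues against that trend as the whole of the rise. Immune cells mixed into the PRL cultures would bring their abundant transcripts, but 14 leukocyte genes moved by a median of -0.0273 CPM while the interferon-stimulated genes gained 104.7 CPM, a share of -0.0261%. Of these 14 genes, RAC2 rose, LYZ fell, 9 lay under 1 CPM in both groups, and 2 are also in the stromal and immune list. A hypothesis is that interferon made in the PRL cultures may have raised these genes, since 3 interferon genes (IFNL1, IFNL2 and IFNL3) had over 3 counts in each PRL library and at most 3 in each control. These counts cannot separate a source of the response from a part of it. Whether prolactin or another property of the transduced cell population lies behind it cannot be told apart, because both coincide with the groups.

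The fall of ribosomal protein genes held under every other scaling tried, where the list's median was at most -0.53 (TPM), and after removal of the GC and length trend (-0.80, against -0.99). That removal also moved the median of all genes to -0.11, from 0.01, so part of the -0.80 is shared by all genes. Genes matched to them fell too, though less at the median. Of 64 other genes matched on length, GC content and control level, 53 fell, with a median log2 fold change of -0.74 (SD 0.50), so that 0.25 of the list's fall lay beyond them. The matched genes were less abundant (median 1193 CPM in controls, against 2548), and a fall of short, abundant transcripts as a class, technical or biological, cannot be told apart from a fall of ribosomal protein genes as such. The oxidative phosphorylation list (median -0.63) was not compared with genes matched to it, and its median fall did not exceed that of these 64 genes. No biological explanation was tested.

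Replication-dependent histone transcripts rose while their usual partners fell. More cells in S phase would raise the DNA replication list, which had a median of -0.83 (SD 0.51), and removal of the GC and length trend left the histone median at 1.38, against 1.02. Different selection of RNA for the libraries of the groups may be involved. The MTRNR2L genes, which resemble mitochondrial ribosomal RNA, had a median log2 fold change of 0.69 (SD 0.23), and 7 of 8 rose, but the other did not pass. The selection of RNA, and whether it differed between the groups, is not given in the sources used here, so this stays open. Other explanations of the histone rise were not tested.

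Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split was the 1 with 8854 changed genes (4554 higher, 4300 lower, 2231 by at least 2-fold). The other splits gave at most 0 in edgeR for each count (at most 139 genes at an unadjusted p under 0.05). Each of them mixes PRL and control libraries on both sides, so the difference between the groups enters the spread within a side. Their counts of 0 therefore say nothing about chance. For camera with its preset correlation the real split gave 16 lists and the highest of these mixed splits 13.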
